A study of Mus musculus with 16 samples.

How the data were processed

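The series holds 16 single-colour expression arrays of total RNA from isolated ILC2s in 6 groups. IL-33 was given intranasally, per the labels, and the sort markers are not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol and labelled with biotin using a Nugen Encore kit. The deposited values are log2 signals, 1 per probe set and array, made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA combines background correction, quantile normalization and probe summary. The versions of these tools and the genome build are not given in the sources used here. The log2 scale of the deposited values was checked against their range. No scanner files were used here, so background and detection could not be reassessed, and the gene coordinates were not used.

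The table holds 41345 probe sets. The probe annotation gave 1 gene symbol for 23521 of them, several for 1814 and none for 16010, and genes were named only from those with 1 symbol. Of these, 23328 matched the reference gene table by Entrez identifier and 0 symbols needed updating. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 22180 genes. A number of genes central to these cells, such as the IL-33 receptor Il1rl1, Areg, Ptgdr2 and Tcf7, were not analysed here.

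Each group mean was fitted to all 16 arrays in 1 linear model with limma 3.58.1 in R 4.3.3, with no trend, no robust option, no filter on dim genes and no replicate block. The model had 10 residual and 6.52 prior degrees of freedom. All groups shared 1 estimate of the spread because the naive and 4-month groups have 2 arrays each. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of a comparison. Changes are differences of group means on the log2 scale with limma's moderated standard error, and all tests are two-sided. RMA gives the probe signals of all arrays the same distribution, so a change in total RNA per cell is not visible, and the narrower range of the naive and 4-month arrays remained after it.

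Gene lists were fixed before the data were examined: 15 functional and 10 cell type marker lists. The red blood cell marker list had 1 measured member and was not tested, which left 24 lists. List shifts were tested with limma's camera at a preset correlation of 0.01, adjusted over 216 tests, and with an estimated correlation and fry as alternatives. Fry tests whether a list's genes move on balance in one direction and does not compare the list with other genes. For each list, members that passed were also counted with p values adjusted over the list alone.

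The rule for named genes was fixed before the data were examined. Per comparison it takes the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, leaving out predicted genes (for the interaction, the 5 largest each way), up to 4 called members of each list with the largest change, and a fixed set of ILC2 genes whether they passed or not. Other genes are named only where said to be chosen after their values were seen.

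The alternatives chosen beforehand were array medians centred, quantile normalization repeated on the deposited values, leaving out genes whose highest group mean was under the 40th percentile of all values, limma's trend and robust options, array weights, fits of only the groups compared, the mean of a gene's probe sets, the replicate number as a block, a log2 change of at least 1 and leaving out each array. Alternatives added after seeing the data were a fit of the 12 arrays of the groups with 3 replicates, the mean of macrophage markers as a covariate, the replicate number as a block within each time point, and leaving out day 4 lung replicates 1 and 2 and week 2 lung replicate 3. The last of these kept naive replicate 1 and the 4-month arrays. Their macrophage marker means were 5.59, 5.50 and 5.12, against 4.90 or less on the day 4 and week 2 lung arrays that remained.

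The procedure was tested on simulated data for 22180 genes with each group's own spread and 200 changed genes. For week 2 against day 4 in the lung, 55% of genes changed by a log2 of 1 and 98% of those changed by 2 were recovered, and 1.92% of calls were of unchanged genes. For 4 months against naive lung the recovery was 47% and 91%, with 68.6% of calls of unchanged genes, and with array weights 9% and 66%, with 5.06% of calls of unchanged genes. For 4 months against week 2 in the lung 12.5% of calls were of unchanged genes. The simulated groups did not differ in signal range, so these shares cover random spread only. The equal-weight fit called too many genes where noisy arrays were compared. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.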

Results

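Gene expression was measured in group 2 innate lymphoid cells (ILC2s), tissue-resident lymphocytes that make type 2 cytokines, isolated from C57BL/6J mice. Lung ILC2s came from naive mice (n = 2 arrays) and from mice treated intranasally with the alarmin cytokine IL-33, at day 4 (n = 3), week 2 (n = 3) and 4 months (n = 2) after the first treatment. ILC2s of the mediastinal lymph node (mLN), which drains the lung, were taken at day 4 (n = 3) and week 2 (n = 3). Each of the 16 arrays was labelled as a biological replicate, and their number limits the precision of every value. The comparisons address how lung ILC2s differ from the naive state while activated and long afterwards, and how ILC2s of the node differ from those of the lung.

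The naive and 4-month arrays stood apart from the rest in quality. The interquartile range of log2 signal, averaged over the arrays of a group, was 2.60 in naive lung and 2.50 at 4 months, against 2.96 at day 4 and 2.93 at week 2 in the lung. The replicates of the naive and 4-month groups correlated at r = 0.937 and r = 0.947 over the genes tested, while the lowest correlation within any of the other groups was 0.977. Arrays with these spreads were simulated once per comparison, with 200 changed genes. Of the calls against naive lung, 35.9% at day 4, 30.5% at week 2 and 68.6% at 4 months were of unchanged genes. These shares stand for 80, 67 and 302 genes, where the real comparisons called 3677, 2134 and 436. As the shares depend on how many genes truly change, and the simulated groups did not differ in signal range, they do not carry over to the real counts. With array weights, which lower the influence of noisy arrays, the same simulations gave 6.12%, 6.56% and 5.06%. Recovery of genes changed by a log2 of 1 then fell from 49%, 66% and 47% to 15%, 35% and 9%. A call lost with array weights is therefore not shown to be false. The count with array weights is given beside each comparison that uses the naive and 4-month groups.

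At day 4 after IL-33, division genes and individual cytokine and receptor genes were higher in lung ILC2s than in naive lung ILC2s. Il1r2, the decoy receptor for IL-1, rose from 3.26 ± 0.14 (SD, n = 2) to 9.12 ± 0.24 (SD, n = 3), a log2 change of 5.86 ± 0.35 (SE, limma adjusted p = 7.25e-08). The cytokine Il6 rose by 4.19 ± 0.35 (adjusted p = 2.62e-06), and Il17rb, a subunit of the IL-25 receptor, rose by 1.95 ± 0.18. The type 2 cytokines Il13 and Il5 rose by 1.28 ± 0.24 and 1.10 ± 0.22 from already high naive levels of 10.38 ± 0.46 and 7.55 ± 0.44. Mki67, a marker of dividing cells, rose by 2.88 ± 0.24 (adjusted p = 2.62e-06). Each of these calls also passed with array weights.

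Of 36 measured cell cycle genes, 31 rose and 0 fell at day 4, with a median change of 1.40 (34 rose when adjusted over the list alone). Examples were Top2a, the DNA topoisomerase of dividing cells, at 2.96 ± 0.31 and Rrm2, a subunit of ribonucleotide reductase, at 2.95 ± 0.34. The list passed limma's camera test with the preset correlation (adjusted p = 1.16e-23) and with an estimated correlation (adjusted p = 0.0344). Of 20 genes of lipid uptake and fatty acid oxidation, 11 rose and 0 fell (13 rose adjusted over the list alone), with a median of 1.04 and an adjusted p = 0.0249 with an estimated correlation. They included the fatty acid binding proteins Fabp5 (2.88 ± 0.50) and Fabp4 (3.85 ± 0.67) and the fatty acid transporter Cd36 (2.52 ± 0.77), whose call was lost with array weights. Fabp5 stood at 5.26 and 7.78 on the naive arrays and at 8.81 or more on the day 4 lung arrays. On day 4 replicates 1, 2 and 3, Fabp4 stood at 7.43, 6.48 and 4.56 and Cd36 at 7.24, 6.84 and 3.53, beside macrophage marker means of 6.25, 6.23 and 4.90. Without the lung arrays high in macrophage transcripts, an alternative chosen after seeing the data that left replicate 3 as the lone day 4 lung array, the median of the lipid list was 0.69, and the differences were 2.29 for Fabp5, 2.25 for Fabp4 and 0.18 for Cd36. Interferon-stimulated genes rose in 16 of 19 cases and fell in 0 (17 and 1 adjusted over the list alone), among them Bst2, the membrane protein tetherin, at 3.42 ± 0.31 and Ifit1 at 2.40 ± 0.39. That list passed with the preset correlation (adjusted p = 6.58e-12) and missed the threshold at an adjusted p = 0.0559 with an estimated correlation.

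Costimulatory and inhibitory receptors and ligands rose in 11 of 21 cases and fell in 1 (11 and 2 adjusted over the list alone). The largest of these were Tnfsf4, which encodes OX40 ligand, at 3.62 ± 0.40, the inhibitory receptor Tigit at 3.40 ± 0.27, Tnfsf8, which encodes CD30 ligand, at 3.34 ± 0.24 and Ctla4 at 2.47 ± 0.39. The list's median was 0.88, with camera adjusted p = 1.40e-05 and an adjusted p = 0.218 with an estimated correlation. Of 13 cytokines and growth factors, 6 rose and 1 fell (7 and 2 adjusted over the list alone, adjusted p = 0.336 with an estimated correlation). Lif fell by 1.17 ± 0.25. Of 12 chemokines, 3 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.141 with an estimated correlation), with Cxcl3 at 3.51 ± 0.31 and Cxcl10 at 2.70 ± 0.41. Glycolysis genes rose in 5 of 15 cases, unfolded protein response genes in 4 of 17 and ribosomal protein genes in 5 of 18, and 0 fell in each of these lists (5, 4 and 7 rose adjusted over the list alone, with 1 ribosomal protein gene falling there). With an estimated correlation their adjusted p values were 0.147, 0.443 and 0.218. The rises of these lists were not told apart from the narrower signal range of the naive arrays. ILC2 receptors did not pass as a list (camera adjusted p = 0.0563), with 5 of 19 higher and 2 lower (8 and 3 adjusted over the list alone). In the list of homing receptors and integrins, which did not pass as a list (camera adjusted p = 0.110), 8 of 25 rose and 4 fell (9 and 4 adjusted over the list alone), including Itgae, the integrin CD103, at 3.93 ± 0.34. The transcription factor Irf4 rose by 2.89 ± 0.28, while Klf2, a regulator of lymphocyte egress, fell by 1.55 ± 0.24. Gata3 and Rora, which direct ILC2 identity, changed by -0.19 ± 0.22 and 0.49 ± 0.20 and did not pass, as was so for Icos (0.32 ± 0.24), Thy1 (-0.39 ± 0.25), Bcl2 (-0.17 ± 0.24) and Csf2 (0.56 ± 0.22).

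Markers of T cells were lower at day 4 than in the naive arrays. Of 11 measured T cell markers, 7 fell and 0 rose (7 and 1 adjusted over the list alone), with a median of -0.87 and an adjusted p = 0.0266 with an estimated correlation. The CD3 chains Cd3d and Cd3e fell by 3.22 ± 0.49 and 3.17 ± 0.27, and Cd8b1 fell by 3.14 ± 0.20. The CD3 chain Cd3g did not fall, at 8.33 and 9.05 on the naive arrays and 8.94, 8.95 and 9.06 at day 4. The mean of the T cell markers was 6.74 and 6.65 on the naive arrays and between 5.20 and 5.52 on the other 14. The cytotoxic cell receptor Klrd1 fell by 4.35 ± 0.38. Genes associated with memory T cells fell in 8 of 22 cases and rose in 2 (8 and 3 adjusted over the list alone, adjusted p = 0.452 with an estimated correlation). Chil3, which macrophages express abundantly, and the chemokine Ccl17 were among the largest rises, at 5.03 ± 1.15 and 5.13 ± 1.16, and varied between replicates: Ccl17 stood at 10.55, 10.24 and 4.41 on day 4 replicates 1, 2 and 3, and the mean of 13 macrophage markers at 6.25, 6.23 and 4.90. The 13 markers as a list did not pass (camera adjusted p = 0.562), and the call of Chil3 was lost with array weights.

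In all, 3677 of 22180 genes were called between day 4 and naive lung at a limma adjusted p under 0.05, of which 2406 were higher and 1271 lower at day 4. With array weights 1627 were called, and in a fit of these groups alone 1380. With array medians centred, 2867 genes were higher and 717 lower. Without day 4 replicate 1 or 2 the number was 2274 or 2419, and without day 4 replicates 1 and 2 and week 2 lung replicate 3, the lung arrays of that period highest in macrophage transcripts, it was 688, an alternative chosen after seeing the data in which the lone day 4 lung array was assumed to vary like the other groups.

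**Figure D1:**
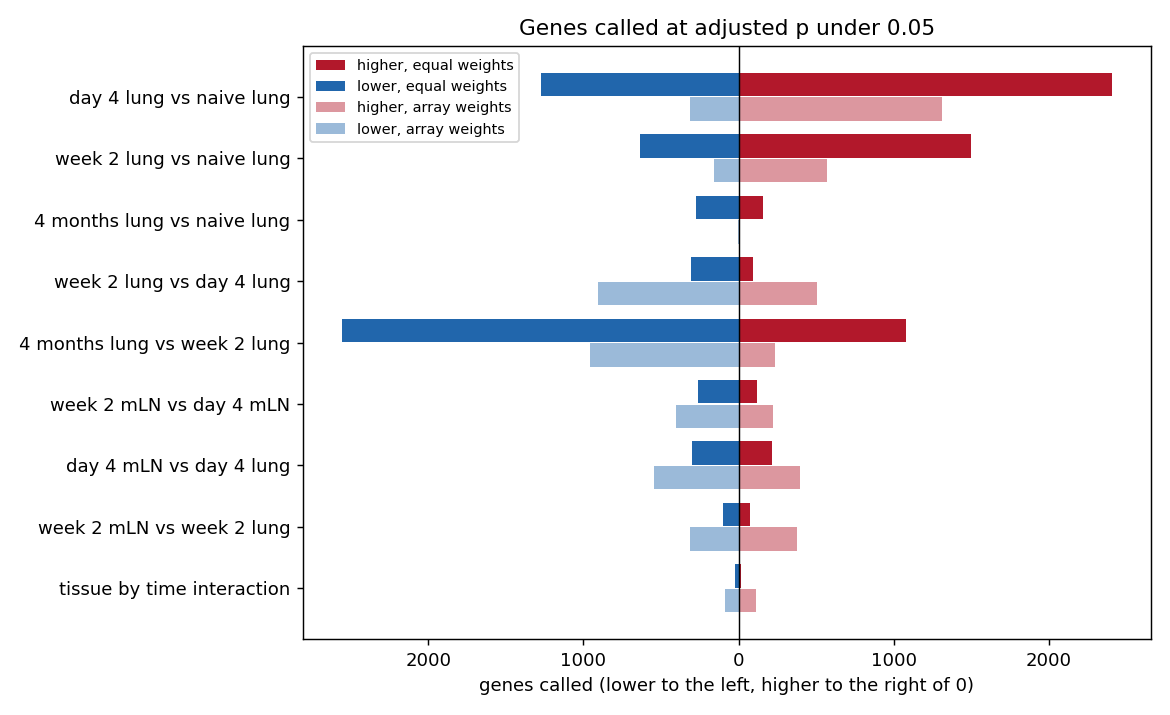
Genes called higher (right of 0) or lower (left of 0) in each of 9 comparisons at a Benjamini-Hochberg adjusted p under 0.05, with all arrays weighted equally (dark bars) and with array weights (pale bars). For 4 months against naive lung, 436 genes were called with equal weights and 4 with array weights.

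At week 2, the cytokine Il6 and the ligand genes Tnfsf8 and Tnfsf18 were higher in lung ILC2s than in naive lung ILC2s. Il6 rose by 3.45 ± 0.35 (limma adjusted p = 4.19e-05), Tnfsf8 by 3.44 ± 0.24 (adjusted p = 9.45e-07) and Tnfsf18, which encodes the ligand of GITR, by 2.69 ± 0.36. Rgs16, a regulator of G protein signalling, rose by 3.33 ± 0.47 and Adgrg7, an adhesion G protein-coupled receptor, by 2.81 ± 0.17. Il17rb rose by 1.91 ± 0.18, and the cytokines Csf2 and Il2 by 1.17 ± 0.22 and 1.33 ± 0.27. These calls passed with array weights too. Il5 rose by 0.97 ± 0.22 (adjusted p = 0.0112), a call lost with array weights, and Il13 (0.61 ± 0.24) and Mki67 (0.59 ± 0.24) did not pass.

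Of 13 cytokines and growth factors 5 rose and 0 fell against naive lung (6 rose adjusted over the list alone, camera adjusted p = 7.20e-05, adjusted p = 0.141 with an estimated correlation). Costimulatory and inhibitory receptors and ligands did not pass as a list (camera adjusted p = 0.0801), with 4 of 21 higher and 1 lower (4 and 1 adjusted over the list alone). ILC2 receptors rose in 3 of 19 cases, cell cycle genes in 5 of 36 and lipid genes in 2 of 20, and 0 fell (6, 5 and 5 rose adjusted over the list alone). Their adjusted p values with an estimated correlation were 0.492, 0.501 and 0.111. The unfolded protein response list shifted up by a median of 0.34 with 0 of 17 members called (0 adjusted over the list alone, adjusted p = 0.377 with an estimated correlation). Over all genes, naive minus week 2 fell with the level in the day 4 lung and mLN groups (Spearman rho -0.560). The rises of these lists were not told apart from the narrower signal range of the naive arrays. Memory T cell associated genes fell in 6 of 22 cases and rose in 2 (9 and 3 adjusted over the list alone, adjusted p = 0.452 with an estimated correlation), with S1pr1, a receptor for egress from tissue, at -1.75 ± 0.22 and Lef1 at -1.49 ± 0.24. Cytotoxic genes fell in 4 of 16 cases (5 adjusted over the list alone, adjusted p = 0.205 with an estimated correlation), with the chemokine Ccl5 at -1.64 ± 0.22 and Nkg7, a granule protein, at -1.73 ± 0.35. ILC3 markers fell in 1 of 8 (2 adjusted over the list alone, adjusted p = 0.205 with an estimated correlation), the receptor Il23r at -1.54 ± 0.22. T cell markers fell in 6 of 11 cases (7 adjusted over the list alone), with an adjusted p = 0.0102 with an estimated correlation, and Cd3e fell by 3.10 ± 0.27. The T cell marker means were 6.74 and 6.65 on the naive arrays and 5.31, 5.30 and 5.35 on the week 2 arrays. The falls of memory T cell associated and cytotoxic genes could not be told apart from other lymphocytes in the naive samples. The number of genes called was 2134, of which 1498 were higher and 636 lower. It was 728 with array weights, 525 in a fit of these groups alone, 1158 with quantile normalization and 1084, 1122 and 1140 without week 2 lung replicates 1, 2 and 3. Without the arrays high in macrophage transcripts it was 683.

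At 4 months, most calls against naive lung were lost with array weights, and those that passed included 3 falls. Il6 stood at 6.14 ± 1.11 (SD, n = 2) against 3.30 ± 0.12 (SD, n = 2) in naive cells, a rise of 2.84 ± 0.38 (limma adjusted p = 0.00194) whose call was lost with array weights. Il17rb rose by 0.91 ± 0.19, Il2 by 1.48 ± 0.29 and the copper transporter Slc31a1 by 1.92 ± 0.42, and these calls were lost likewise. Slc31a1 stood at 4.26 and 2.24 on the naive arrays and at 5.18 and 5.16 on the 4-month arrays. Cd8b1 fell by 2.94 ± 0.22, Cd3e by 2.76 ± 0.30 and Alox5, the 5-lipoxygenase of leukotriene synthesis, by 2.37 ± 0.30, and these passed with array weights, as did the rise of Igkv5-43, an immunoglobulin light chain segment, by 3.38 ± 0.26. The falls of the T cell markers Cd8b1 and Cd3e could not be told apart from T cells in the naive samples. Whether Igkv5-43 rose in ILC2s or through other cells in the 4-month samples was not tested. Il5 (0.62 ± 0.24), Il13 (0.05 ± 0.27), Csf2 (0.84 ± 0.24), Klrg1 (-0.34 ± 0.26) and Mki67 (-0.63 ± 0.26) did not pass.

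T cell markers fell in 5 of 11 cases (6 adjusted over the list alone), with a median of -1.27 and an adjusted p = 0.00611 with an estimated correlation. A further 5 lists passed only with the preset correlation. Cytokines rose in 2 of 13 cases (3 adjusted over the list alone) and B cell markers in 0 of 9 (3 adjusted over the list alone). Lymphoid transcription factors fell in 2 of 24, memory T cell associated genes in 3 of 22 and interferon-stimulated genes in 2 of 19 (3, 6 and 6 adjusted over the list alone). With an estimated correlation the adjusted p values of these lists were 0.275, 0.416, 0.452, 0.377 and 0.517. The T cell marker means were 6.74 and 6.65 on the naive arrays and 5.25 and 5.42 on the 4-month arrays. The falls of T cell markers, lymphoid transcription factors and memory T cell associated genes could not be told apart from other lymphocytes in the naive samples. In all 436 genes were called, 159 higher and 277 lower, against 4 with array weights, 0 in a fit of these groups alone and 783 with quantile normalization. With array medians centred, 128 genes were higher and 453 lower, and the median of all genes lay at -0.12. At an unadjusted p under 0.05 the planned limma fit gave 3773 genes. Leaving out naive replicate 1 or 4-month replicate 2 gave 1300 or 1412, where the lone array was assumed to vary like the other groups. Without 4-month replicate 1 the direction turned, with 175 higher and 128 lower of 303 genes.

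Of the genes called at day 4, 142 were called in the same direction at 4 months against the same naive arrays, 54 higher and 88 lower, and 25 were called in opposite directions. Independent lists of these sizes would share 17.2 higher and 15.9 lower. Among 100 simulated sets of unchanged groups, the mean overlap was 2.23 and the highest 16. Across genes, which are not independent replicates, the changes correlated at r = 0.259 against a simulated r = 0.656, and their covariance was 0.0722 against a simulated 0.102, a difference of -0.0300. For week 2 and 4 months the overlap was 146 genes, 59 higher and 87 lower, with 4 in opposite directions, against 10.7 and 7.94 for independent lists and a simulated mean of 1.91 and highest of 10. Their changes correlated at r = 0.370 against a simulated r = 0.674, with a covariance of 0.0866 against a simulated 0.102, a difference of -0.0156. No gene was changed in the simulations, which makes the calling threshold stricter, so the simulated overlaps are no measure for lists of the real sizes. The covariances lay below the simulated ones, but the simulated groups did not differ in signal range. The real range was wider at day 4 and week 2 than in naive lung and narrower at 4 months. Such opposite shifts can lower the covariance, so it does not decide whether a change was shared across all genes. The naive group has 2 arrays and could not be split, so part or all of any excess may come from the shared controls. With array weights the overlaps were 4 genes, 1 of them higher, and 3 genes, 0 of them higher. Without naive replicate 1 they were 585 and 579, and without naive replicate 2 304 and 288. Without 4-month replicate 1 most shared genes were higher, 86 of 144 for day 4 and 79 of 136 for week 2.

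**Figure D2:**
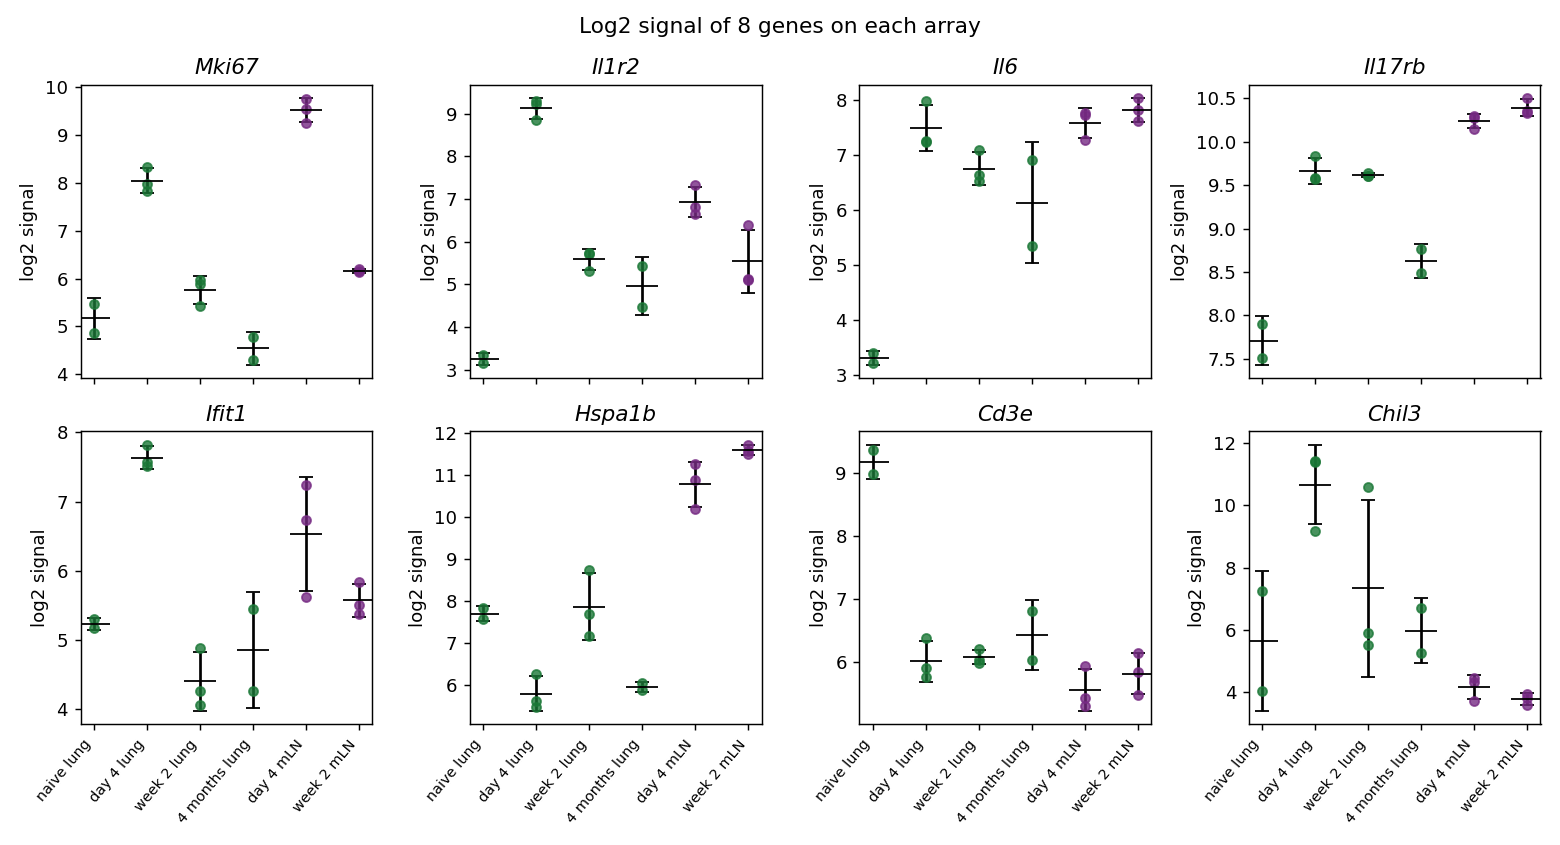
Log2 signal of 8 genes on each array (points; green for lung, purple for mLN) with the group mean (bar) and SD (whiskers), in groups of 2 or 3 arrays. Mki67 stood at 8.05 at day 4 in the lung and 9.52 in the mLN, and Chil3 was high on a part of the lung arrays.

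Between day 4 and week 2, division and interferon-stimulated genes fell in lung ILC2s. Mki67 fell by 2.29 ± 0.22 (limma adjusted p = 2.50e-05), from 8.05 ± 0.26 to 5.76 ± 0.29 (SD, n = 3 each), and Ube2c, a mitotic ubiquitin-conjugating enzyme, fell by 3.30 ± 0.31. Il1r2 fell by 3.53 ± 0.32, the secreted peptide gene Tff1 by 4.22 ± 0.25 and the linker histone H1f5 by 4.28 ± 0.55. Il2, Tnf and Lif rose by 2.07 ± 0.24, 1.62 ± 0.32 and 1.75 ± 0.22, and Nmur1, the neuromedin U receptor, rose by 1.26 ± 0.21. Il5 (-0.13 ± 0.19), Il13 (-0.67 ± 0.22), Il6 (-0.74 ± 0.31) and Il17rb (-0.05 ± 0.16) did not pass.

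Of 36 cell cycle genes 21 fell and 0 rose (27 fell adjusted over the list alone), with a median of -1.07 and an adjusted p = 0.0102 with an estimated correlation. Of 19 interferon-stimulated genes 14 fell and 0 rose (18 fell adjusted over the list alone), with a median of -1.46 and an adjusted p = 0.00611 with an estimated correlation, among them Ifit1 at -3.24 ± 0.35 and Isg15 at -2.37 ± 0.31. Chemokines fell in 4 of 12 cases (7 adjusted over the list alone), also with an adjusted p = 0.00611 with an estimated correlation, and included Cxcl3 at -3.35 ± 0.28 and Ccl5 at -1.68 ± 0.20. The chemokine Ccl17 stood at 10.55, 10.24 and 4.41 on day 4 lung replicates 1, 2 and 3, following the macrophage marker means of 6.25, 6.23 and 4.90. Costimulatory and inhibitory receptors fell in 8 of 21 cases (10 fell and 3 rose adjusted over the list alone, adjusted p = 0.141 with an estimated correlation), with Tigit at -3.04 ± 0.24, Ctla4 at -2.64 ± 0.35 and Lag3 at -2.05 ± 0.23. Lipid genes fell in 1 of 20 (4 adjusted over the list alone, adjusted p = 0.0613 with an estimated correlation). Immediate early and stress genes rose in 3 of 22 cases and fell in 2 (12 and 2 adjusted over the list alone, adjusted p = 0.347 with an estimated correlation), with Hspa1b, an inducible heat shock protein, at 2.07 ± 0.33, Jun at 1.21 ± 0.27 and Egr2 at -1.28 ± 0.21. Without the lung arrays high in macrophage transcripts, which left replicate 3 as the lone day 4 lung array, the median of this list was 0.08.

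The ribonuclease gene Rnase2a fell by 5.32 ± 0.83 and Ccl17 by 4.43 ± 1.03, while the 13 macrophage markers as a list did not pass (median -0.39, camera adjusted p = 0.0589). The number of genes called was 401, 93 higher and 308 lower at week 2. It was 1409 with array weights, and 182, 213, 201, 182 and 227 without day 4 lung replicates 1 and 2 and week 2 lung replicates 1, 2 and 3. With the macrophage marker mean as a covariate, chosen after seeing the data, it was 234. Leaving out the arrays high in macrophage transcripts left a lone day 4 lung array, so calls lost there do not tell their source.

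From week 2 to 4 months in the lung, most called genes were lower. Tnfsf8 fell by 2.60 ± 0.24 (limma adjusted p = 1.69e-05), Itgae by 2.76 ± 0.34, Rgs16 by 2.64 ± 0.47, the Notch ligand Jag1 by 3.01 ± 0.26 and the inhibitory receptor Lilrb4a by 3.15 ± 0.23. The receptor genes Il18r1, Kit and Il17rb fell by 1.85 ± 0.25, 1.35 ± 0.22 and 0.99 ± 0.18. Mki67 fell by 1.22 ± 0.24. These calls held with array weights, which change the spread assigned to an array and not its signal range. With quantile normalization repeated on the deposited values, 39 of the 58 named calls of this comparison held. A part of these falls may come from the narrower signal range of the 4-month arrays. The largest rises, Ifna9 (3.85 ± 0.41) and Lce1g (3.84 ± 0.31), an interferon alpha gene and a cornified envelope gene, were from 1.48 ± 0.22 and 2.30 ± 0.37 (SD, n = 3), near the bottom of the signal range.

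Unfolded protein response genes fell in 7 of 17 cases (11 adjusted over the list alone), with Herpud1, a stress-induced membrane protein, at -0.95 ± 0.19 and a list median of -0.60 (camera adjusted p = 0.000122, adjusted p = 0.275 with an estimated correlation). ILC2 receptors fell in 5 of 19, cell cycle genes in 5 of 36, glycolysis genes in 3 of 15, lipid genes in 4 of 20 and ribosomal protein genes in 1 of 18 (5, 5, 5, 5 and 0 adjusted over the list alone). Their adjusted p values with an estimated correlation were 0.517, 0.585, 0.205, 0.188 and 0.297. Over all genes the change fell with the level in the day 4 lung and mLN groups (Spearman rho -0.637). The falls of these lists were not told apart from the narrower signal range of the 4-month arrays. B cell markers rose in 2 of 9 cases and NK cell and ILC1 markers in 1 of 7 (5 and 3 adjusted over the list alone, adjusted p = 0.309 and 0.305 with an estimated correlation). The club cell secretoglobin Scgb1a1 fell by 5.12 ± 1.33, having stood at 11.02, 10.17 and 6.31 on the week 2 arrays. Of 3633 called genes 1076 were higher and 2557 lower at 4 months, and 532 of those higher were predicted or unnamed genes or belonged to receptor and small RNA families. With array medians centred 655 were higher and 3758 lower, and the median of all genes lay at -0.12. The number was 1196 with array weights, 1721 in a fit of these groups alone, 1421 with quantile normalization, 793 and 5588 without 4-month replicates 1 and 2, and 2126, 1933 and 1997 without week 2 lung replicates 1, 2 and 3, where a lone 4-month array was assumed to vary like the other groups. Without the arrays high in macrophage transcripts it was 1073.

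In the mLN, ILC2s at week 2 had far lower division transcripts than at day 4. Mki67 fell by 3.36 ± 0.22 (limma adjusted p = 7.48e-08), from 9.52 ± 0.25 to 6.16 ± 0.03 (SD, n = 3 each), cyclin A2 (Ccna2) by 4.47 ± 0.24 and the kinetochore genes Nuf2 and Knl1 by 3.93 ± 0.25 and 3.95 ± 0.23. Cdkn1a, a cell cycle inhibitor, rose by 2.32 ± 0.34 and Hes1, a Notch target, by 2.25 ± 0.22. Tnfsf8 rose by 1.35 ± 0.21 and Il2 by 1.07 ± 0.24. Cpa3, a carboxypeptidase of mast cells and basophils, fell by 3.38 ± 0.36. Il5 (-0.14 ± 0.19), Il13 (0.36 ± 0.22), Il6 (0.23 ± 0.31) and Il17rb (0.16 ± 0.16) did not pass.

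Cell cycle genes fell in 31 of 36 cases and rose in 0 (34 fell adjusted over the list alone), with a median of -2.50 and an adjusted p = 0.00170 with an estimated correlation. Immediate early and stress genes rose in 11 of 22 cases and fell in 0 (17 rose adjusted over the list alone), with a median of 1.15 (camera adjusted p = 7.93e-26, adjusted p = 0.0559 with an estimated correlation). Among them were Nr4a3 at 2.53 ± 0.55, Atf3 at 2.46 ± 0.47, Klf4 at 2.45 ± 0.41 and Egr1 at 2.20 ± 0.32, transcription factors induced by receptor signals and stress. Day 4 replicate 3 stood apart in both tissues. Over mLN replicates 1, 2 and 3 at day 4, Nr4a3 stood at 5.66, 5.47 and 7.93, Atf3 at 5.73, 5.92 and 7.81 and Klf4 at 5.52, 5.42 and 6.75, and on lung replicate 3 they stood at 10.38, 8.87 and 8.41, against at most 8.19, 7.04 and 6.74 on the other day 4 lung arrays. The calls of Nr4a3 and Atf3 were lost without day 4 mLN replicate 1 (adjusted p = 0.147 and 0.0592) or replicate 2 (Nr4a3 at an adjusted p = 0.163), and held without replicate 3. Interferon-stimulated genes fell in 2 of 19 (11 adjusted over the list alone, adjusted p = 0.0902 with an estimated correlation). Cytokines rose in 1 of 13, costimulatory receptors rose in 1 and fell in 1 of 21, memory T cell associated genes rose in 1 and fell in 1 of 22, homing receptors fell in 2 of 25, and 0 of 18 ribosomal protein genes passed. Adjusted over the list alone, cytokines rose in 6 cases, costimulatory receptors rose in 3 and fell in 2, memory genes rose in 5 and fell in 1, homing receptors rose in 1 and fell in 5, and 0 ribosomal protein genes passed. With an estimated correlation the adjusted p values of these 5 lists were 0.275, 0.377, 0.416, 0.309 and 0.275. In all 379 genes were called, 117 higher and 262 lower at week 2. The number was 629 with array weights and 247 without day 4 mLN replicate 2.

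At day 4, mLN ILC2s had higher division transcripts than lung ILC2s and lower transcripts of a part of the costimulatory and inhibitory receptors and ligands. Mki67 was higher by 1.47 ± 0.22 (limma adjusted p = 0.000793) and Ccna2 by 2.39 ± 0.24. Hspa1b and Hspa1a, inducible heat shock proteins, were higher by 4.97 ± 0.33 and 4.57 ± 0.49, Deptor, an inhibitor of mTOR, by 3.32 ± 0.29 and the eotaxin receptor Ccr3 by 2.42 ± 0.36. Il4 was higher by 1.38 ± 0.18, and Il13 was lower in the mLN (-1.23 ± 0.22). Rgs16 (-5.27 ± 0.42), the ion channel Asic3 (-4.22 ± 0.21) and the stem cell factor receptor Kit (-2.28 ± 0.20) were lower in the mLN. Il6 (0.10 ± 0.31), Il5 (-0.52 ± 0.19) and Gata3 (-0.16 ± 0.19) did not pass.

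Cell cycle genes were higher in the mLN in 27 of 36 cases and lower in 0 (33 and 0 adjusted over the list alone), with a median of 1.52 and an adjusted p = 0.00611 with an estimated correlation. Costimulatory and inhibitory receptors were lower in 10 of 21 cases (12 adjusted over the list alone, adjusted p = 0.0131 with an estimated correlation), with Ctla4 at -2.63 ± 0.35, Tigit at -2.28 ± 0.24, Tnfsf8 at -2.16 ± 0.21 and Pdcd1, which encodes PD-1, at -1.92 ± 0.28. Chemokines were lower in 3 of 12 (6 adjusted over the list alone, adjusted p = 0.0120 with an estimated correlation), including Ccl3 at -3.14 ± 0.56. On day 4 lung replicates 1, 2 and 3 Ccl3 stood at 7.31, 7.03 and 4.64 and Ccl17 at 10.55, 10.24 and 4.41, moving with the macrophage marker means of 6.25, 6.23 and 4.90. With the macrophage covariate the Ccl3 difference was -1.16 and its call was lost (adjusted p = 0.480). The macrophage marker mean was lower on every mLN array than on every lung array, so this does not tell macrophage RNA from a tissue difference. Immediate early and stress genes were lower in 7 of 22 cases and higher in 2 (10 and 2 adjusted over the list alone, adjusted p = 0.377 with an estimated correlation), with Egr2 at -2.76 ± 0.21. Cytokines were lower in 3 of 13 and higher in 1 (6 and 1 adjusted over the list alone). Lymphoid transcription factors were lower in 3 of 24 and higher in 1 (4 and 1), lipid genes lower in 2 of 20 (5) and interferon-stimulated genes lower in 0 of 19 (4), with the values adjusted over the list alone in parentheses. With an estimated correlation the adjusted p values of these 4 lists were 0.147, 0.448, 0.131 and 0.239.

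At day 4, Chil3 was lower in the mLN than in the lung (-6.51 ± 1.03), as were the chemokine Ccl6 (-4.69 ± 0.76), Fabp4 (-4.12 ± 0.60) and Ccl24 (-4.20 ± 0.46), and Chil3 ranged from 9.19 to 11.43 over the day 4 lung arrays. Of 13 macrophage markers 2 were lower and 1 higher (7 and 1 adjusted over the list alone, camera adjusted p = 3.66e-06, adjusted p = 0.305 with an estimated correlation). In all 517 genes were called, 217 higher and 300 lower in the mLN. The number was 939 with array weights and 182 with the macrophage marker mean as a covariate, the latter chosen after seeing the data. It was 344, 333 and 254 without day 4 lung replicates 1 and 2 and day 4 mLN replicate 2. The macrophage marker mean was at most 4.51 on the mLN arrays and at least 4.64 on the lung arrays. The covariate thus also takes out part of the tissue difference, and the lost calls do not tell their source. Leaving out the lung arrays high in macrophage transcripts left a lone day 4 lung array, so it does not tell the source either.

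At week 2, Deptor, Il4 and Ccr3 were higher and Rgs16, Kit and Il2 lower in ILC2s of the mLN than in those of the lung. Deptor was higher in the mLN by 4.44 ± 0.29 (limma adjusted p = 3.85e-07), Atp8a2, a phospholipid flippase, by 3.47 ± 0.17, Il4 by 2.54 ± 0.18 and Ccr3 by 2.53 ± 0.36. Hspa1a and Hspa1b were higher by 3.81 ± 0.49 and 3.72 ± 0.33, and Klrg1, an inhibitory receptor of mature ILC2s, by 0.98 ± 0.21. Rgs16 (-3.21 ± 0.42), Ccl3 (-3.11 ± 0.56), Kit (-2.32 ± 0.20), Il2 (-1.86 ± 0.24) and Tnf (-1.75 ± 0.32) were lower in the mLN. Il5 (-0.52 ± 0.19), Il13 (-0.21 ± 0.22), Il6 (1.07 ± 0.31) and Mki67 (0.40 ± 0.22) did not pass.

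Interferon-stimulated genes had a median of 0.50 in the mLN against the lung, with 1 of 19 passing, Rtp4 at 1.54 ± 0.33 (7 adjusted over the list alone, adjusted p = 0.111 with an estimated correlation). Cytokines were lower in 3 of 13 and higher in 1 (5 and 2 adjusted over the list alone, adjusted p = 0.347 with an estimated correlation). Cell cycle and ribosomal protein genes shifted up by medians of 0.24 and 0.22 with 0 of 36 and 0 of 18 passing (0 in both adjusted over the list alone, adjusted p = 0.452 and 0.0738 with an estimated correlation). Macrophage markers had a median of -0.53 (0 of 13 called), granulocyte markers of -0.42 (0 of 10) and epithelial, endothelial and stromal markers of -0.22 (1 of 12), with camera adjusted p = 0.000987, 0.0111 and 0.0168 and adjusted p = 0.442, 0.306 and 0.232 with an estimated correlation. Adjusted over the list alone 2 macrophage and 0 granulocyte markers were lower, and 2 stromal and epithelial markers were lower and 1 higher. The lists of dendritic cell, basophil and mast cell, and T cell markers did not pass (camera adjusted p = 0.699, 0.300 and 0.414). Scgb1a1 was lower in the mLN (-5.74 ± 1.19). In all 173 genes were called, 74 higher and 99 lower. The direction turned with array weights, with 377 of 692 higher, in a fit of these groups alone, with 161 of 310 higher, with array medians centred, with 80 of 158 higher, and with the replicate number as a block within each time point, chosen after seeing the data, with 174 of 338 higher. The number was 88, 91 and 109 without week 2 lung replicates 1, 2 and 3, 90 and 94 without week 2 mLN replicates 1 and 2, and 74 without the lung arrays high in macrophage transcripts.

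The change from day 4 to week 2 was compared between the tissues by an interaction term, the mLN change minus the lung change. Cell cycle genes fell further in the mLN, with 9 of 36 passing (24 adjusted over the list alone), a median interaction of -1.20 and an adjusted p = 0.0120 with an estimated correlation, among them Ccna2 at -2.48 ± 0.34 (limma adjusted p = 0.00423). Costimulatory and inhibitory receptors had positive interactions in 4 of 21 cases (9 adjusted over the list alone, adjusted p = 0.0266 with an estimated correlation): Ctla4 at 3.10 ± 0.50, Lag3 at 2.05 ± 0.32, Tigit at 1.96 ± 0.34 and Cd83 at 1.64 ± 0.30. Interferon-stimulated genes and chemokines had positive medians of 0.93 and 1.13 with 0 of 19 and 0 of 12 members passing over all genes (11 and 9 adjusted over the list alone, adjusted p = 0.0266 and 0.00611 with an estimated correlation). On the day 4 lung arrays the chemokines Ccl3 and Ccl17 moved with the macrophage marker mean, standing at 4.64 and 4.41 on replicate 3, where that mean was 4.90, and at 7.03 and 10.24 or higher on the other arrays. Lymphoid transcription factors, memory T cell associated genes, lipid genes and ribosomal protein genes passed only with the preset correlation, with 0 members passing in each (3, 0, 0 and 0 adjusted over the list alone, adjusted p = 0.442, 0.487, 0.309 and 0.0570 with an estimated correlation). So did immediate early and stress genes, with 1 of 22 passing (1 adjusted over the list alone, adjusted p = 0.416 with an estimated correlation). Egr2 (2.34 ± 0.29) and Itgae (2.41 ± 0.43) had positive interactions and Ccr2 (-1.40 ± 0.22) a negative one. In all 40 genes passed, 15 positive and 25 negative, against 115 positive and 90 negative with array weights and 55 positive and 47 negative in a fit of these groups alone. Without day 4 lung replicate 3, 33 were positive and 19 negative, and with the replicate number as a block within each time point, chosen after seeing the data, 45 were positive and 23 negative. Positive interactions were also the larger part without day 4 lung replicate 2 (12 of 20) and without week 2 lung replicate 3 (10 of 19). With the macrophage covariate, chosen after seeing the data, 17 of 33 were positive. The number called was 20 and 12 without day 4 lung and day 4 mLN replicate 2. It was 19, 11 and 19 without week 2 lung replicates 1, 2 and 3, and 23, 25 and 22 without week 2 mLN replicates 1, 2 and 3. Without the lung arrays high in macrophage transcripts it was 13, 11 positive and 2 negative.

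**Figure D3:**
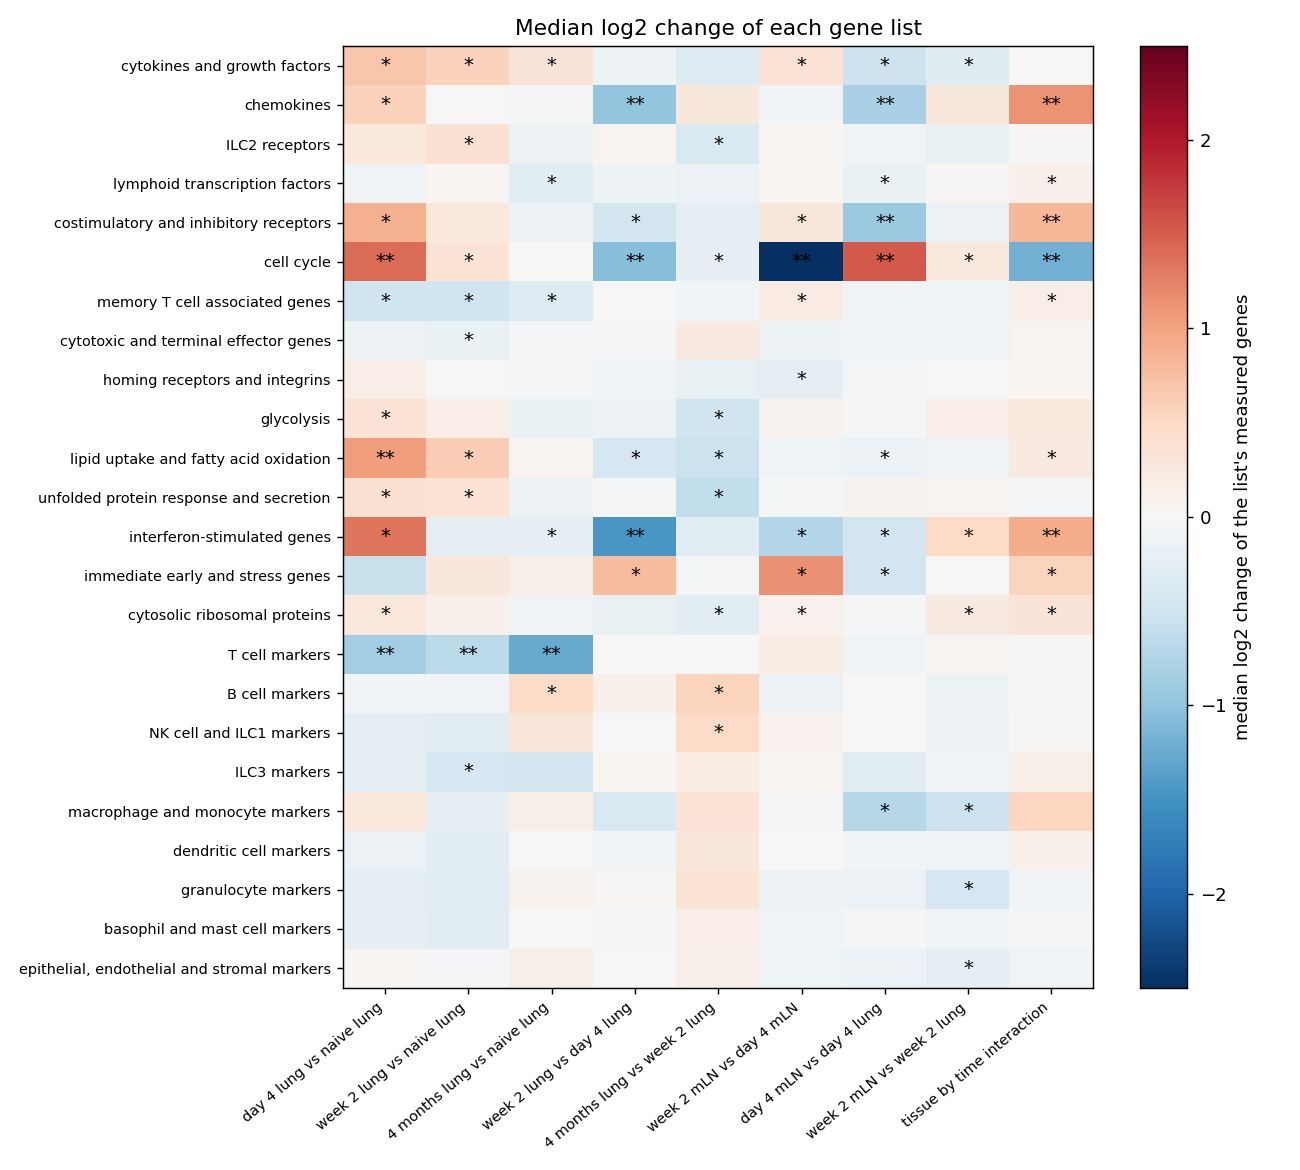
Median log2 change of each of 24 gene lists (vertical) in each of 9 comparisons (horizontal), red for higher and blue for lower in the group named at the start. A single asterisk marks a call with camera's preset correlation and a double asterisk a call that also held with an estimated correlation, as for cell cycle genes at week 2 against day 4 in the mLN (median -2.50).

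Over the 9 comparisons 216 list tests were made, of which 73 passed with the preset correlation and 16 of these with an estimated correlation. Those 16 were T cell markers in each comparison with naive lung, cell cycle genes in 5 comparisons, chemokines in 3, costimulatory receptors and interferon-stimulated genes in 2 each and lipid genes in 1. Dendritic cell markers and basophil and mast cell markers passed in 0 of 9 comparisons with camera, with 2 and 0 at an unadjusted p under 0.05 and 0 and 2 with fry.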

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

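Chosen after the result was seen were the tests of the signal range of the naive arrays and of the single outlying 4-month array, the splits of the labels for the interaction, and the alternatives with a macrophage covariate or without arrays high in macrophage transcripts.

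The interaction stood out because the change from day 4 to week 2 differed between mLN and lung in 40 genes. The gene values were Ccl24 at 3.77, Tff1 at 3.65, Bex1 at 3.47, Ctla4 at 3.10, Asic3 at 2.77, Ccna2 at -2.48, Nuf2 at -2.27, Kif23 at -2.21, Kif14 at -2.18 and Hmmr at -2.02 (log2). Ccl24 stood at 9.22, 8.59 and 6.58 on day 4 lung replicates 1, 2 and 3, where the macrophage marker means were 6.25, 6.23 and 4.90. The list medians were 1.13 for chemokines, 0.12 for lymphoid transcription factors, 0.83 for costimulatory and inhibitory receptors, -1.20 for cell cycle genes, 0.16 for memory T cell associated genes, 0.23 for lipid genes, 0.93 for interferon-stimulated genes, 0.56 for immediate early and stress genes and 0.32 for ribosomal protein genes. Of these lists the chemokine, costimulatory, cell cycle and interferon lists passed with an estimated correlation. Of 100 splits of the day 4 and week 2 labels within each tissue, drawn after the mean time effect of both tissues was taken out, 2 gave as many genes, the real one at 40 included, and the highest of the others gave 61, above the real count. With the time effect left in, 5 of the 100 gave as many and the highest gave 121, but relabelling then turns a time effect into an interaction. As this form is void and the one without the time effect was chosen after its result was seen, chance was not taken as excluded for this count, which lay between 11 and 52 when 1 array was left out.

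For the remaining comparisons of 3 against 3 arrays the 10 possible splits are too few for a share under 0.05. For week 2 against day 4, 1 of the 10 splits gave as many genes in the lung, the real one at 401 with the highest other at 58, and 1 in the mLN, 379 against 0. For mLN against lung it was 1 at day 4, 517 against 0, and 1 at week 2, 173 against 0.

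Signal also appeared in probe sets outside the gene comparisons: 207 of 1814 probe sets with several genes and 1195 of 16010 with no gene name were called between day 4 and naive lung.

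T cell transcripts were higher on the naive lung arrays. The 4-month arrays had a signal range as narrow, yet the median T cell marker change from naive to 4 months was -1.27, which argues against the narrow range as the source. T cells in the naive samples remain open: 18 further T cell transcripts had a median naive minus week 2 difference of 0.72 (bootstrap SE 0.377), above all 10000 lists matched on expression, of which the highest was 0.218, with 11 of the 18 higher and Cd27, Cd28, Ccr7 and Lef1 also on functional lists. Cd3e stood at 9.18 on the naive and 6.07 on the week 2 lung arrays, while Cd3g stood at 8.33 and 9.05 on the naive and 8.31, 8.34 and 7.99 on the week 2 lung arrays. The labels name no sort markers that would remove such cells, and transcription of these genes by naive ILC2s themselves may also account for it and was not tested.

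Macrophage transcripts were high on part of the day 4 lung arrays. Within groups, over 10 lung arrays, 19 further macrophage transcripts followed the macrophage marker mean with a median r of 0.727, against at most 0.449 for 10000 matched lists, so macrophage RNA in the isolated lung samples may account for it. The marker Chil3 reached 11.43 on day 4 replicate 2 and 10.61 on week 2 replicate 3, and Lyz2 averaged 8.40 in day 4 lung and 5.03 in day 4 mLN. The labels name no sort markers that would remove macrophages. Expression of these genes by activated ILC2s remains open as untested.

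Of the genes called between 4 months and week 2 in the lung, most were lower at 4 months. Across genes, which are not independent replicates, the change fell with the level in the day 4 lung and both mLN groups at a Spearman rho of -0.637, against 0.0680 for day 4 minus week 2, so the narrower signal range of the 4-month arrays may account for much of the count, and for naive minus week 2 rho was -0.560, so it may also bear on the comparisons with naive lung. Of the brighter genes 2521 were lower and 206 higher, and of the dimmer genes 36 lower and 870 higher. Without 4-month replicate 1, the array with the narrowest range, 793 genes were called, and without replicate 2 5588. A true difference at 4 months stays open and cannot be separated from array quality by these values.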

How the results depend on the processing

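Chosen only after the results were seen were the fit of the 12 arrays of the groups with 3 replicates, the macrophage covariate, the replicate block within each time point and the omission of the lung arrays high in macrophage transcripts. Of 410 named gene results, 0 turned direction under the alternatives of the fit chosen before the data were examined. In each of these alternatives 212 stayed past the threshold. The trend and robust options and the fits of only the groups compared leave differences of group means unchanged. Direction could not turn there. Outside the interaction, genes picked as the largest changes between groups that did not overlap could not turn when an array was left out either. The result on direction is no test of stability in these cases. With dim genes left out 409 had a value, since the filter removed Klri2 at day 4 against naive lung, and named genes were not tested against the threshold on the change. Of 73 list results, 40 stayed past the threshold in each alternative of the fit. Where counts moved the cause was not tested, except that a threshold on the change can only lower them, by construction. The number of arrays limits these results, and signal over background was not measured here.

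With quantile normalization 1158 genes were called for week 2 against naive lung, 783 for 4 months against naive lung and 1421 for 4 months against week 2 lung, with 259 shared by day 4 and 4 months and 235 by week 2 and 4 months. With array weights the counts were 1627, 728 and 4 for day 4, week 2 and 4 months against naive lung, 1409 for week 2 against day 4 lung, 1196 for 4 months against week 2 lung, 629 for week 2 against day 4 mLN, 939 and 692 for mLN against lung at day 4 and week 2, and 205 for the interaction, with 4 and 3 shared. In fits of only the groups compared they were 1380, 525 and 0 for day 4, week 2 and 4 months against naive lung, 1721 for 4 months against week 2 lung, 310 for mLN against lung at week 2 and 102 for the interaction, with 0 and 0 shared. With a log2 change of at least 1 they were 1614 and 879 for day 4 and week 2 against naive lung, 263 for week 2 against day 4 lung and 1106 for 4 months against week 2 lung, with 86 and 97 shared. The 73 list calls fell to 16 with an estimated correlation.

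In the 12 arrays of the groups of 3 the counts were 689 for week 2 against day 4 lung, 792 and 342 for mLN against lung at day 4 and week 2 and 102 for the interaction. With the macrophage covariate they were 234 for week 2 against day 4 lung and 182 for mLN against lung at day 4. The difference of S100a9 between mLN and lung at day 4 then turned to 0.042, and that of the macrophage list to 0.13 at day 4 and 0.084 at week 2, as the covariate is made from that list. The covariate was also lower on every mLN array than on every lung array, so it takes out part of the tissue difference. Leaving out the lung arrays high in macrophage transcripts left a lone day 4 lung array, so a lower count there may reflect fewer arrays. Without the lung arrays high in macrophage transcripts the counts were 688 and 683 for day 4 and week 2 against naive lung, 46 for week 2 against day 4 lung, 1073 for 4 months against week 2 lung, 201 and 74 for mLN against lung at day 4 and week 2 and 13 for the interaction, and Itgax at day 4 against naive lung turned to -0.029.

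Leaving out 1 array at a time gave 2274 to 3308 genes for day 4 against naive lung, 1084 to 2274 for week 2 against naive lung, 303 to 1412 for 4 months against naive lung, 182 to 460 for week 2 against day 4 lung, 793 to 5588 for 4 months against week 2 lung, 247 to 380 for week 2 against day 4 mLN, 254 to 449 and 88 to 146 for mLN against lung at day 4 and week 2, and 11 to 52 for the interaction. The shared calls ranged from 104 to 585 for day 4 and 4 months and from 98 to 579 for week 2 and 4 months, and the list calls from 62 to 77. A lone array left in a group was assumed to vary like the other groups.

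With the replicate number as a replicate block 3562, 1902, 445, 441, 3298, 403, 522, 193 and 46 genes were called in the comparisons in the order of the plot of called genes, with 143 and 134 shared and 74 list calls, none of them over 1.5 times from the counts without it. Of 410 named gene calls 19 were lost with it. Deviations of arrays with the same number correlated at -0.104 to 0.184, with 2 of 36 pairs over 0.1, and not every pair passed 0.1, so the numbers were not taken to pair the arrays. The 36 pairs include arrays of different time points, so this cannot exclude a pairing of lung and mLN arrays within a time point. As a hint towards pairing from the data, 10 of 16 arrays correlated best with an array of their own number, where 5.43 would by chance. Lung and mLN replicate 3 at day 4 correlated at 0.184, against 0.0920 and 0.0285 for replicates 1 and 2 and at most 0.0925 for unlike numbers. At week 2 lung and mLN replicates 1, 2 and 3 correlated at 0.0281, 0.0120 and 0.0188, against at most 0.0127 for unlike numbers. With the number as a replicate block within each time point, 747 and 338 genes were called for mLN against lung at day 4 and week 2 and 68 for the interaction.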

Other observations

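The genes named here were chosen only after their values were seen, and no further tests were run. Against the same naive arrays, 49 genes were called higher at day 4, week 2 and 4 months alike and 74 lower. Besides Il6, those higher included Tnfsf18 (2.45, 2.69 and 1.78 at the successive times), the inflammatory caspase Casp1 (2.30, 1.96 and 1.42), the transcription factor Batf3 (2.38, 1.06 and 1.33) and Slc31a1 (2.18, 1.73 and 1.92). Slc31a1 differed widely between the naive arrays, at 4.26 and 2.24. These sets share the naive arrays, and with limma's array weights the overlap of day 4 and 4 months was 1 gene higher and 3 lower and that of week 2 and 4 months 0 higher and 3 lower. None of the 49 genes, those named included, was then called at all these times. Each naive array had a weight of 0.439 and each 4-month array 0.442, so the changes at 4 months stayed the same and the spread assigned to them differed. In the simulation for 4 months against naive lung, array weights recovered 9% of genes changed by a log2 of 1. The lost calls thus do not decide whether the set comes from the naive arrays, which remains open.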
